A study of Homo sapiens with 6 samples.

How the data were processed

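Newly made RNA was measured by 4sU-seq in RPE1 cells, in 6 libraries of 3 groups: wild type untreated, wild type treated with H2O2 and NuMA knockdown treated with H2O2, with 2 libraries each. Groups were taken from the sample labels, per the labels' treatment and genotype. Wild type cells had no doxycycline and knockdown cells had it, per the labels. The series' design text also speaks of untreated knockdown cells, of binding of NuMA to chromatin and of a map of oxidative damage, and these were not analysed here. The labels number the libraries 1 and 2 in each group without saying what a number marks.

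RNA was isolated with Trizol and libraries were made by a standard Illumina protocol, per the labels' protocols, which give no dose, labelling time or strandedness. STAR 2.5, DESeq2, DESeq and build hg38 are named per the submitters' processing notes, without their roles or settings. The tool that counted reads, its strand setting and the annotation release were not given in the sources used here. Without a known strand setting, reads of a gene and of an antisense or overlapping partner cannot be told apart. The authors deposited 2 tables of 60448 genes, one per comparison, each with a shorter table of the genes under an adjusted p of 0.05.

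Each deposited table held, per gene, a signal value for each of 2 groups, pooled over libraries, whose unit is not stated in its header or labels. The deposited log2 fold change equalled the log2 ratio of those 2 values. The deposited p-value was given for every gene, and the adjusted p for 18522 genes in the H2O2 comparison and 18266 in the knockdown comparison. The adjusted p equalled a Benjamini-Hochberg adjustment over the genes that had one. Which program gave the p-values is not stated.

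The signal values were worked out from their steps. Genes without reads held one constant divided by a length, and low genes moved in steps of that constant, so a value was the mean count of the libraries plus an added count of 1, divided by gene length and multiplied by a factor common to both groups of a table. The value for H2O2-treated wild type cells differed between the tables by a constant ratio of 1.07. A whole-number length that made all 3 group values whole counts or whole counts divided by 2, within a tolerance of 1e-06, was found for all 60448 genes, and 86.0% of these lengths equalled the mean transcript length of the annotation rounded down. Lengths of 2.59% of the genes were raised so that no mean count fell below 0. The values fix a length only up to a whole multiple. For 85.7% of the tested genes the length was settled by its match to the annotation's mean transcript length. For the others, C11orf96 among them, the mean counts may be off by a common multiple. That leaves the fold changes as they are but not the totals.

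Recovered mean counts summed to 14786612 per library in untreated wild type cells, 18341732 in H2O2-treated wild type cells and 16827872 in the knockdown. The depth of single libraries is unknown. The log2 ratio of these totals was 0.31 for the H2O2 comparison and -0.12 for the knockdown comparison, and 0.24 and -0.09 over genes with a settled length only, while the median log2 fold change of genes with at least 50 mean counts was 0.29 over 11647 genes and -0.29 over 11600 genes. The deposited p-values tested the unscaled fold change: among genes with at least 500 mean counts, the median p was 0.962 in 104 genes within 0.02 of a log2 fold change of 0 and 0.172 in 132 genes within 0.02 of the median in the H2O2 comparison. In the knockdown comparison these medians were 0.938 in 145 genes and 0.00960 in 176 genes.

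The planned tests, on values per library, could not be run on 1 value per group. The fallback written for tables of fold changes and p-values was used, the authors' own deposited test described and not refitted. Genes were called at a deposited adjusted p under 0.05. An implied standard error was computed as the size of the log2 fold change divided by the normal quantile of its p-value. For 187 genes of the H2O2 comparison and 243 of the knockdown comparison, whose fold change or p gave none, the median over 101 neighbours in mean count was used. The implied standard error had a median of 0.29 over tested genes in the H2O2 comparison and 0.24 in the knockdown comparison. Over genes with more than 500 mean counts the implied coefficient of variation between libraries was 14.2% and 7.05%.

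After the data were seen, the fold changes were centred on the median of tested genes with at least 50 mean counts and tested again with the implied standard error, a normal test and Benjamini-Hochberg adjustment. The shift was a factor of 1.22 in both comparisons. Values printed as log2 changes of single genes are relative to that median gene unless the authors' deposited table is named. Further alternatives scaled the fold changes by the recovered total counts, of all genes or of those with a settled length.

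Gene lists, the named-gene rule, the tests and the alternatives, other than the scalings, the removal of trends, the ranks and the other inter-gene correlation, were fixed before the data were examined. The rule named NUMA1, then per comparison the 8 protein-coding genes with the largest rise and the 8 with the largest fall under an adjusted p of 0.05 with a mean value at or above the median over tested genes, which was 5.84 in the H2O2 table and 5.38 in the knockdown table, and then up to 4 members of each list with the smallest adjusted p. Members named outside this rule were chosen after their values were seen. Some members of the lists are not reported here by name.

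The 20 lists were immediate early genes, NRF2 targets, p53 targets, heat shock genes, ATF4 and unfolded protein response genes, inflammatory NF-kB targets, interferon response genes, single-strand break and base excision repair, replication-dependent histones, mitosis and G2/M, S phase and replication, cholesterol synthesis and uptake, SRF and YAP targets of the cytoskeleton, ribosomal proteins, mitochondrially encoded mRNAs, RNA polymerase II pausing and elongation, and markers of differentiated retinal pigment epithelium, fibroblasts, epithelia and neurons. They came from textbook knowledge, and the study was also recalled to discuss immediate early genes. Each was tested with cameraPR of limma 3.58.1 in R 4.3.3, on the deposited p-value turned into a signed normal statistic, with an inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 20 lists of a comparison. A correlation estimated from the data needs values per library, so a correlation of 0.05 was tried in its place. Members were counted over all genes tested and adjusted over the list alone. Some genes belong to more than 1 list, among them FEN1, ATF3, SESN2 and CTGF, so the list tests are not independent of each other.

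The fold changes of both comparisons were correlated across genes and their calls overlapped, with the overlap of independent lists and with 100 seeded simulations of unchanged groups against the shared libraries beside them, over all genes and within each list. Gene spans, transcript GC content, gene classes and coordinates came from the GENCODE release 29 annotation of hg38, in which 56868 gene IDs of the tables were found. Span was available for 99.1% of the tested genes. Fold changes were related to span by Spearman correlation and by medians of 5 equal groups of genes. Permutation tests were two-sided with 100000 resamples.

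The recovery of lengths, the centred calls, the list test, the removal of a trend and the partial correlation were tested on simulated data. The other steps were not tested in this way. Lengths were found, up to a whole multiple, for 2000 of 2000 simulated genes. Of 100 genes changed 2-fold, 61 were called in the simulated H2O2 comparison and 86 in the simulated knockdown comparison, and of 100 genes changed 4-fold 98 and 100 were called. Among unchanged genes 4 of 18319 and 10 of 18049 were called. The simulated p-values were made in the way the centred test assumes, and as many genes were raised as lowered. These numbers therefore cannot show that the deposited p-values behave in that way or that the median gene was unchanged in the data. A list of changed genes was called and a list of unchanged genes was not, in both.

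Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for all other steps. The alternatives tried were a stricter threshold of 0.01, a minimum of 2-fold, no filter and 2 filters on low values, the scalings, other measures of gene length, removal of the trend with span or GC content, ranks in place of the statistic and the other inter-gene correlation. Genes without an adjusted p were left out of the tests, except with no filter, which took in all genes with at least 1 count.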

Results

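Newly made RNA was measured by 4sU-seq in RPE1 cells, an immortalised human line derived from the retinal pigment epithelium. In this assay cells take up 4-thiouridine, a uridine analogue that marks RNA made during the labelling time, and the marked RNA is collected and sequenced. The 6 libraries fell into 3 groups of 2: wild type untreated, wild type treated with hydrogen peroxide (H2O2), and NuMA knockdown treated with H2O2. NuMA, encoded by NUMA1, is a large nuclear protein that organises the poles of the mitotic spindle. The knockdown was induced with doxycycline, which the wild type cells did not receive, so the drug and the knockdown formed 1 factor. An untreated knockdown was not analysed here, so the effect of the knockdown cannot be compared between untreated and treated cells. The labels give no dose of H2O2 and no times, and they do not say that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

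The deposited values were 1 per gene and group, with no value per library. Mean counts recovered from them summed to 14786612 per library in untreated wild type cells, 18341732 in H2O2-treated wild type cells and 16827872 in the knockdown. The authors' log2 fold changes carried no scaling for depth, and the median gene with at least 50 mean counts stood at 0.29 after H2O2 and at -0.29 in the knockdown. Changes are therefore given relative to that median gene, with the standard error that the authors' p-value implies and with adjusted p-values recomputed after centring. Genes are said to have risen or fallen where the adjusted p was under 0.05 in the authors' deposited table and again after centring. List p-values from limma's cameraPR were computed on the authors' deposited, uncentred statistic unless another setting is named, even where they stand beside a centred median. Among genes with over 500 mean counts the implied standard error had a median of 0.21 on the log2 scale in the H2O2 comparison and 0.11 in the knockdown comparison. Members named because a count was 5 or lower were chosen after their values were seen.

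NUMA1 lies on chromosome 11 from 72002864 to 72080693 (hg38, minus strand, protein coding). It had mean counts of 1168 in untreated wild type, 1571 in H2O2-treated wild type and 933.5 in H2O2-treated knockdown libraries. Between the H2O2-treated groups NUMA1 fell by 0.46 ± 0.12 (standard error) on the log2 scale, a 1.37-fold decrease with an adjusted p of 0.00114. In wild type cells its log2 change after H2O2 was 0.14 ± 0.21 (adjusted p = 0.669), less than its error. In the authors' deposited table NUMA1 had a log2 fold change of -0.75 in the knockdown, with an adjusted p of 1.42e-08.

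The first comparison asked which newly made RNAs changed when wild type cells were treated with H2O2. Among the gene lists, those of immediate early genes, cholesterol synthesis and the actin cytoskeleton genes controlled by SRF and YAP were called higher by the list test. The lists of mitosis, ribosomal proteins and mitochondrially encoded mRNAs were called lower, with 38 of 74 ribosomal protein genes lower in the authors' deposited table. FOS, a transcription factor gene induced within minutes of many stimuli, went from 80.5 to 7668.5 mean counts, a log2 rise of 6.27 ± 0.22 (adjusted p = 2.96e-169). SERPINB2, which encodes a plasminogen activator inhibitor, fell by 5.23 ± 0.25 on the log2 scale, from 1922 to 61.5 mean counts (adjusted p = 4.61e-93).

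After H2O2, 6725 of 18522 tested genes were called in the authors' deposited table, 4947 higher and 1778 lower, so that 73.6% of the called genes were higher. Centring on the median gene left 3067 higher and 2921 lower (51.2% higher), and scaling by the total counts left 2963 higher and 3011 lower (49.6% higher, or 55.0% with the totals of genes with a settled length). After centring, 1696 of the higher genes and 1583 of the lower genes differed from the median gene by at least 2-fold.

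The 8 protein-coding genes with the largest rises included EGR4, ARC, FOS and FOSB, which are immediate early genes. EGR4 went from 1 to 527.5 mean counts, too few in untreated cells for a fold change. ARC, on chromosome 8 from 142611044 to 142614472, rose by 6.66 ± 0.28 on the log2 scale (adjusted p = 4.53e-119). FOSB rose by 6.08 ± 0.20, from 156.5 to 13025 mean counts (adjusted p = 5.05e-198). RASD1, C11orf96, SCD and HMGCS1 completed the 8, with log2 rises of 5.85 ± 0.43, 5.43 ± 0.68, 4.77 ± 0.19 and 4.66 ± 0.23. SCD encodes stearoyl-CoA desaturase, which makes monounsaturated fatty acids. The 8 largest falls were those of SERPINB2, ELMO3, OSR1, G0S2, NDUFA11, GCKR, PLEKHF1 and CGB8, with log2 changes between -5.23 and -3.05. NDUFA11, which encodes an accessory subunit of respiratory complex I, went from 1254.5 to 154.5 mean counts. CGB8 belongs to a cluster of near-identical chorionic gonadotropin genes, so its counts are uncertain.

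**Figure D1:**
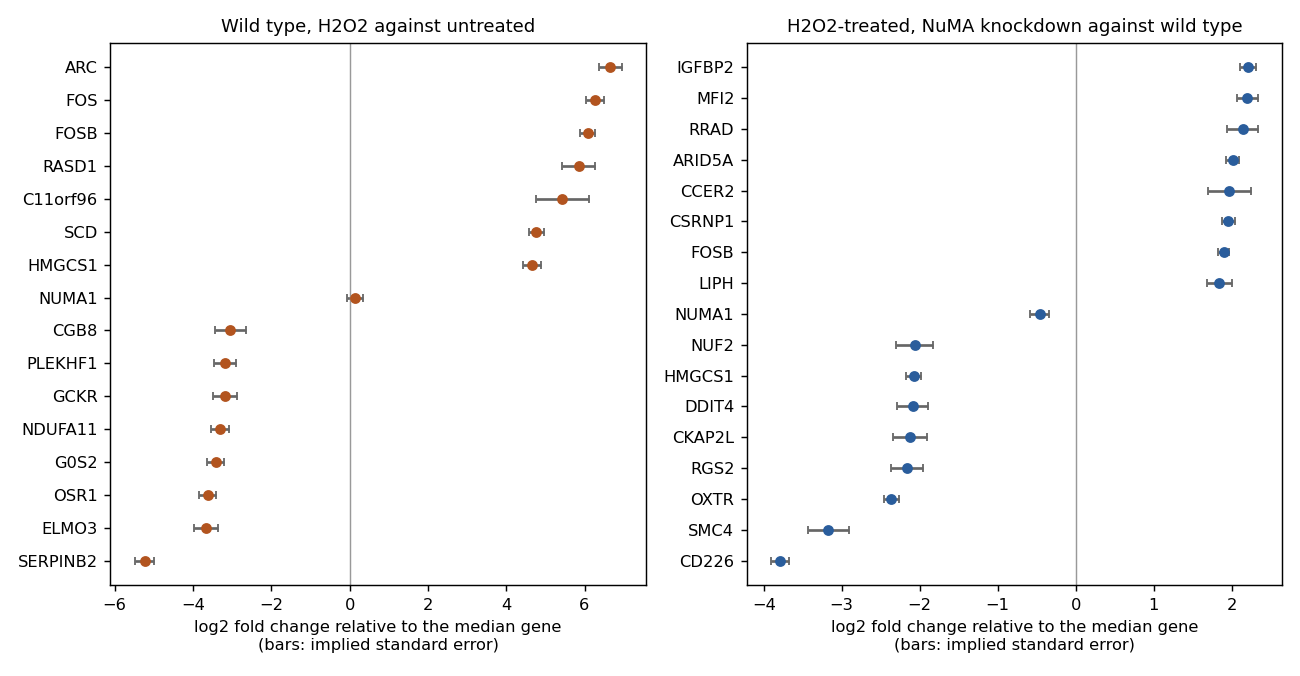
Log2 fold change relative to the median gene for NUMA1 and for the protein-coding genes with the largest rises and falls in each comparison, with bars of 1 implied standard error and without EGR4, which had 1 mean count in untreated libraries. The left panel runs from -5.23 for SERPINB2 to 6.66 for ARC, and the right panel from -3.79 for CD226 to 2.21 for IGFBP2.

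Of 34 immediate early genes, 27 were called higher and 0 lower after H2O2 in the authors' deposited table (27 and 0 adjusted over the list alone). After centring, 26 were higher and 2, FOSL1 and CYR61, were lower, and the list median was 1.22 (limma's cameraPR on the deposited statistic, adjusted p = 1.27e-43). ATF3, a stress-induced transcription factor gene, rose by 4.34 ± 0.21 on the log2 scale. Among 20 tested genes of cholesterol synthesis and uptake, 18 were higher and 0 lower in the authors' deposited table (19 and 0 adjusted over the list alone). The same number, 18, was higher after centring, with a list median of 2.22 (limma's cameraPR on the deposited statistic, adjusted p = 9.27e-48). HMGCS1, which encodes the synthase that feeds HMG-CoA into the mevalonate pathway, lies on chromosome 5 from 43289395 to 43313512 and went from 122.5 to 3820.5 mean counts. MSMO1 and DHCR7, both of the later sterol steps, rose by 3.22 ± 0.19 and 2.92 ± 0.19.

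Targets of SRF and YAP in the actin cytoskeleton were called higher in 19 of 20 cases in the authors' deposited table (19 adjusted over the list alone). After centring, 17 were higher and 1, CYR61, was lower, with a median of 1.22 (limma's cameraPR on the deposited statistic, adjusted p = 6.47e-21). ACTA2, the smooth muscle actin gene, rose by 3.95 ± 0.19 and TGFB2 by 2.43 ± 0.22 on the log2 scale. Heat shock genes were higher in 11 of 19 cases in the authors' deposited table (13 higher and 1 lower, HSPE1, adjusted over the list alone), and 9 were higher and 1, HSPE1, lower after centring. Their median was 0.50 (limma's cameraPR on the deposited statistic, adjusted p = 0.000819). HSPA1A and HSPA1B, whose near-identical sequences make the split of their counts uncertain, rose by 2.11 ± 0.21 and 1.48 ± 0.20. Replication-dependent histone genes, also near-identical copies, were higher in 11 of 18 cases in the authors' deposited table (11 adjusted over the list alone) and in 9 after centring. The histone list was called at an adjusted p of 0.0259 with limma's cameraPR, and had an adjusted p of 0.0996 with an inter-gene correlation of 0.05 in place of 0.01.

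Genes of mitosis and G2/M were lower after H2O2 in 18 of 26 cases and higher in 1, ANLN, in the authors' deposited table (19 lower and 1 higher adjusted over the list alone). After centring 22 were lower, with a median of -1.18 (limma's cameraPR on the deposited statistic, adjusted p = 5.44e-13). AURKB, a mitotic kinase gene, fell by 2.35 ± 0.22 and CDC20, an activator of the anaphase-promoting complex, by 2.11 ± 0.21 on the log2 scale. Ribosomal protein genes were lower in 38 of 74 cases in the authors' deposited table (42 lower and 1 higher, RPS23, adjusted over the list alone), and 61 were lower after centring, with a median of -0.81 (limma's cameraPR on the deposited statistic, adjusted p = 8.53e-15). RPS21 and RPL35 fell by 1.34 ± 0.20 and 1.24 ± 0.19, and their many processed pseudogenes leave some counts uncertain. Mitochondrially encoded mRNAs were lower in 11 of 13 cases in the authors' deposited table (12 adjusted over the list alone) and in 12 after centring, with a median of -1.36 (limma's cameraPR on the deposited statistic, adjusted p = 5.57e-13). MT-ND3 fell by 2.54 ± 0.19 and MT-CO3 by 1.66 ± 0.20, and nuclear copies of mitochondrial sequence leave part of their counts uncertain. All 13 lie on the mitochondrial genome and may change together, so they are not 13 independent cases. The list test with its small preset correlation does not allow for this, and its p-value may be far too small. The share of counts on mitochondrial genes was 14.3% in untreated and 6.35% in H2O2-treated wild type cells.

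Among 29 targets of p53, 14 were called higher and 3, DDB2, PHLDA3 and AEN, lower in the authors' deposited table (14 and 3 adjusted over the list alone), and 11 were higher and 4 lower after centring. The list had an adjusted p of 0.0272 with limma's cameraPR, of 0.107 after centring and of 0.130 with an inter-gene correlation of 0.05. BBC3, which encodes the pro-apoptotic protein PUMA, rose by 1.47 ± 0.20 and ZMAT3 by 1.36 ± 0.20 on the log2 scale. Targets of ATF4 and of the unfolded protein response were higher in 13 of 25 cases and lower in 3, TRIB3, SLC7A11 and STC2, in the authors' deposited table (14 and 3 adjusted over the list alone), and higher in 8 and lower in 5 after centring. That list had an adjusted p of 0.0149 with limma's cameraPR, of 0.0716 after centring and of 0.0972 with an inter-gene correlation of 0.05. DDIT4, an inhibitor of mTORC1 signalling, rose by 2.05 ± 0.25.

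NRF2 targets, the genes of the classical antioxidant response, were not called as a list after H2O2 (limma's cameraPR on the deposited statistic, adjusted p = 0.877). Of 26 tested members, 10 were higher and 3, SLC7A11, TXN and AKR1C3, lower in the authors' deposited table (11 and 3 adjusted over the list alone), and after centring 3 were higher, ME1, FTL and SLC48A1, and 6 lower. ME1 rose by 0.99 ± 0.22 on the log2 scale, and TXNRD1 stood at 0.38 ± 0.20 (adjusted p = 0.127). Single-strand break and base excision repair genes were higher in 4 of 26 cases, PARG, TDP2, NEIL2 and UNG, and lower in 4, XRCC1, MUTYH, MPG and FEN1, in the authors' deposited table (4 and 4 adjusted over the list alone). As a list they were not called (adjusted p = 0.110 with limma's cameraPR), but they were after centring, with 0 higher, 7 lower and an adjusted p of 0.0397. XRCC1, the scaffold of single-strand break repair, fell by 1.37 ± 0.21.

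The remaining lists were not called after H2O2. In the authors' deposited table, inflammatory NF-kB targets had 8 of 21 higher and 5 lower, IL6, BIRC3, IL1B, IL1A and IRF1 (9 and 5 adjusted over the list alone). Interferon response genes had 5 of 21 higher and 2 lower, IFIT3 and IFI44L (4 and 1, IFIT3, adjusted over the list alone). S phase genes had 4 of 23 higher, MCM4, MCM6, GINS1 and UHRF1, and 2 lower, CDT1 and FEN1, in the authors' deposited table (4 and 2 adjusted over the list alone). Genes of RNA polymerase II pausing and elongation had 5 of 25 higher, HEXIM1, CTR9, AFF4, ELL2 and TCEA1, and 4 lower, CDK9, CDK12, CCNT2 and ELL (5 and 4 adjusted over the list alone). After centring the higher and lower members were 4 and 5 for NF-kB, 3 and 5 for interferon, 1, MCM6, and 4 for S phase, and 1, TCEA1, and 8 for elongation, so that in all 4 lists more members were lower than higher. With limma's cameraPR these lists had adjusted p-values of 0.7997, 0.695, 0.685 and 0.459. CXCL8 rose by 1.64 ± 0.23 on the log2 scale, IL1B fell by 2.37 ± 0.25, and CDK9, the kinase of the elongation factor P-TEFb, fell by 1.46 ± 0.21. The medians of the interferon, S phase and elongation lists were above 0 in the deposited scale and at -0.21, -0.02 and -0.13 relative to the median gene; with the trend of fold change with gene span removed, that of the S phase list was 0.01.

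Markers of other cell states were looked at for RNA of cells other than RPE1. In the authors' deposited table, markers of differentiated retinal pigment epithelium had 1 of 6 higher, BEST1, and 1 lower, OTX2, and fibroblast markers had 3 of 11 higher, PDGFRB, COL1A1 and FAP, and 1 lower, COL5A1. Epithelial markers had 4 of 6 higher, KRT7, KRT8, KRT18 and KRT19, and neuronal markers had 2 of 8 higher, TUBB3 and SYP (adjusted over the list alone, 1 and 1, 3 and 1, 5 and 0 with CDH1 added, and 2 and 0). With limma's cameraPR none of these 4 lists was called, at adjusted p-values of 0.843, 0.843, 0.0718 and 0.708, but the epithelial list was called with the trend with gene span removed (adjusted p = 0.0467). After centring, 1 epithelium marker was higher and 1 lower, 2 fibroblast markers were higher and 2 lower, 2 epithelial markers, KRT8 and KRT19, were higher, and 2 neuronal markers were higher and 1 lower. PDGFRB went from 407.5 to 3987 mean counts, a rise past the threshold in both tests. For the NRF2, NF-kB, fibroblast and differentiated epithelium lists the direction of the test was opposite to that of the list median.

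The second comparison asked which newly made RNAs differed between H2O2-treated cells with and without the NuMA knockdown. Only the knockdown cells had doxycycline, so every difference below, that of mitochondrial and ATF4 genes included, may come from the drug or from the loss of NuMA. The lists of DNA replication, mitosis, cholesterol synthesis and the actin cytoskeleton were called lower in the knockdown. Those of ribosomal proteins, mitochondrially encoded mRNAs, p53 targets and ATF4 targets were called higher, with 14 of 29 p53 targets and 12 of 25 ATF4 targets higher in the authors' deposited table. CD226, which encodes an immune cell adhesion receptor, lies on chromosome 18 from 69831158 to 69961803 and fell by 3.79 ± 0.12 on the log2 scale, from 3622 to 213.5 mean counts (adjusted p = 4.88e-231). IGFBP2, a binding protein of insulin-like growth factors on chromosome 2 from 216632828 to 216664436, rose by 2.21 ± 0.10, from 1671 to 6312.5 mean counts (adjusted p = 8.90e-103).

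In the knockdown, 6362 of 18266 tested genes were called in the authors' deposited table, 1244 higher and 5118 lower, so that 80.4% were lower. Centring on the median gene left 2829 higher and 2637 lower (48.2% lower), and scaling by the total counts left 1800 higher and 3920 lower (68.5% lower, or 72.3% with the totals of genes with a settled length). After centring, 496 of the higher genes and 708 of the lower genes differed from the median gene by at least 2-fold.

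The 8 largest rises in the knockdown were those of IGFBP2, MFI2, RRAD, ARID5A, CCER2, CSRNP1, FOSB and LIPH, with log2 changes between 1.85 and 2.21. FOSB went from 13025 to 39704.5 mean counts and CSRNP1 from 1553 to 4935. The 8 largest falls were those of CD226, SMC4, OXTR, RGS2, CKAP2L, DDIT4, HMGCS1 and NUF2. SMC4, a core subunit of condensin, fell by 3.17 ± 0.26 on the log2 scale, from 374 to 33 mean counts (adjusted p = 4.71e-32). OXTR, the oxytocin receptor gene, fell by 2.36 ± 0.10 (adjusted p = 1.01e-131). NUF2, which encodes a kinetochore protein, fell by 2.06 ± 0.23 and DDIT4 by 2.09 ± 0.20.

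S phase and replication genes were called lower in 23 of 23 cases in the authors' deposited table (23 adjusted over the list alone) and in 21 after centring, with a median of -1.09 (limma's cameraPR on the deposited statistic, adjusted p = 4.19e-27). MCM6, a subunit of the replicative helicase, fell by 1.73 ± 0.13 on the log2 scale and RRM2, of ribonucleotide reductase, by 0.96 ± 0.10. Genes of mitosis were lower in 25 of 26 cases in the authors' deposited table (25 adjusted over the list alone) and in 22 after centring, with a median of -0.92 (limma's cameraPR on the deposited statistic, adjusted p = 4.65e-21). ANLN and MKI67 fell by 1.72 ± 0.11 and 1.55 ± 0.12. Cholesterol synthesis genes were lower in 18 of 20 cases in the authors' deposited table (19 adjusted over the list alone) and in 15 after centring, with a median of -0.45 (limma's cameraPR on the deposited statistic, adjusted p = 6.49e-17). HMGCS1 fell by 2.08 ± 0.10, from 3820.5 to 738 mean counts, and MSMO1 by 0.49 ± 0.08. Targets of SRF and YAP were lower in 17 of 20 cases and higher in 1, CNN1, in the authors' deposited table (17 and 1 adjusted over the list alone), and 13 were lower and 2 higher after centring, with a median of -0.43 (limma's cameraPR on the deposited statistic, adjusted p = 5.19e-23). TGFB2 fell by 1.61 ± 0.09 and CTGF by 1.03 ± 0.07.

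Ribosomal protein genes were higher in the knockdown in 49 of 74 cases and lower in 3, RPL17, RPL26 and RPL41, in the authors' deposited table (52 and 3 adjusted over the list alone). After centring 68 were higher and 2, RPL26 and RPL41, lower, with a median of 0.62 (limma's cameraPR on the deposited statistic, adjusted p = 1.80e-23). RPL9 rose by 1.35 ± 0.07 on the log2 scale. Mitochondrially encoded mRNAs were higher in 11 of 13 cases in the authors' deposited table (12 adjusted over the list alone) and in 12 after centring, with a median of 0.96 (limma's cameraPR on the deposited statistic, adjusted p = 1.30e-19). MT-CO3 and MT-CO1 rose by 1.48 ± 0.07 and 1.46 ± 0.08, and mitochondrial genes took 10.99% of the counts. As after H2O2, pseudogenes and nuclear copies leave part of the counts of both lists uncertain. The 13 mitochondrial mRNAs are again not independent cases, so the p-value of their list may be far too small.

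Targets of p53 were higher in 14 of 29 cases and lower in 5, GADD45A, FAS, XPC, PLK2 and PMAIP1, in the authors' deposited table (14 and 5 adjusted over the list alone). After centring 16 were higher and 4, FAS, XPC, PLK2 and PMAIP1, lower, with a median of 0.54 (limma's cameraPR on the deposited statistic, adjusted p = 1.03e-06). CDKN1A, the cell cycle inhibitor p21, rose by 1.15 ± 0.07 on the log2 scale and SESN2 by 1.23 ± 0.09. ATF4 and unfolded protein response genes were higher in 12 of 25 cases and lower in 4, DDIT4, HSPA5, SEL1L and SLC7A11, in the authors' deposited table (12 and 4 adjusted over the list alone). After centring 17 were higher and 2, DDIT4 and HSPA5, lower, with a median of 0.45 (limma's cameraPR on the deposited statistic, adjusted p = 5.62e-07). ATF3 rose by 1.42 ± 0.07 and PPP1R15A by 1.20 ± 0.08. Interferon response genes were higher in 5 of 21 cases, ISG15, IFIT1, OASL, IFI6 and IRF7, and lower in 3 in the authors' deposited table (5 and 3 adjusted over the list alone), and higher in 6 and lower in 2 after centring. Their median was 0.64 (limma's cameraPR on the deposited statistic, adjusted p = 0.00244), and ISG15 rose by 1.22 ± 0.11.

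Immediate early genes went both ways in the knockdown, with 14 of 34 higher and 14 lower in the authors' deposited table (14 and 14 adjusted over the list alone). After centring 16 were higher and 9 lower, with a median of 0.30, and the list had an adjusted p of 0.000175 with limma's cameraPR and of 0.449 with ranks in place of the statistic. The list is a general one, but the study was recalled to discuss such genes when it was written, so their direction in the knockdown is not independent evidence. ARC rose by 1.71 ± 0.08 on the log2 scale and JUND, chosen after its value was seen, by 1.53 ± 0.09, whereas KLF4 and FOS, chosen the same way, fell by 1.07 ± 0.14 and 0.71 ± 0.08. Inflammatory NF-kB targets were lower in 10 of 21 cases and higher in 0 in the authors' deposited table (11 and 0 adjusted over the list alone), but after centring 8 were lower and 5, RELB, NFKB2, IL1B, IL1A and PTGS2, higher. Their median was -0.72, and the list had an adjusted p of 0.00244 with limma's cameraPR and of 0.0999 with ranks. NFKBIA, the inhibitor of NF-kB, fell by 1.85 ± 0.09.

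Heat shock genes were lower in 9 of 19 cases and higher in 4, DNAJB1, BAG3, CRYAB and HSPB8, in the authors' deposited table (11 and 5, with HSPB1, adjusted over the list alone). They had an adjusted p of 0.00244 with limma's cameraPR but of 0.290 after centring, when 6 were higher and 6 lower. Their median was -0.05 relative to the median gene and 0.09 with the trend with GC content removed. HSPA8, the constitutive HSP70 chaperone, fell by 1.59 ± 0.07 on the log2 scale and HSPH1 by 1.16 ± 0.12. Repair genes were lower in 16 of 26 cases and higher in 2 in the authors' deposited table (17 and 2 adjusted over the list alone), and lower in 10 and higher in 5 after centring, with an adjusted p of 0.0115 by limma's cameraPR, of 0.0644 after centring and of 0.0711 with an inter-gene correlation of 0.05. FEN1 and PARP1 fell by 1.19 ± 0.12 and 0.63 ± 0.12. FEN1 also belongs to the S phase list, so the falls of the repair and S phase lists are not fully separate results.

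The other lists were not called in the knockdown. In the authors' deposited table, elongation genes had 14 of 25 lower and 1, ELL, higher (15 and 1 adjusted over the list alone), NRF2 targets had 11 of 24 lower and 3, HMOX1, OSGIN1 and MAFG, higher (12 and 4, with FTL, adjusted over the list alone), and histone genes had 1 of 18, HIST1H1C, higher and 1, HIST1H4H, lower (1 and 1 adjusted over the list alone). After centring, 9 elongation genes were lower and 6 higher, 5 NRF2 targets lower and 6 higher, and 1 histone gene lower and 2 higher. With limma's cameraPR their adjusted p-values were 0.0793, 0.543 and 0.208, and the elongation list was called with ranks in place of the statistic (adjusted p = 0.0348). HMOX1, which encodes haem oxygenase, rose by 1.52 ± 0.09 on the log2 scale, and NQO1, another NRF2 target, fell by 0.85 ± 0.09. Markers of differentiated retinal pigment epithelium had 0 of 7 called in the authors' deposited table, where 1 was lower at an unadjusted p under 0.05. Fibroblast markers had 4 of 9 lower, FAP, PDGFRB, TWIST1 and COL6A3, epithelial markers had 3 of 6 lower, KRT8, KRT18 and KRT19, and 1 higher, CLDN4, and neuronal markers had 3 of 8 lower, TUBB3, MAP2 and SYP, with the same numbers adjusted over the list alone. After centring, 3 fibroblast markers were lower and 1 higher, 2 epithelial markers lower and 1 higher, and 1 neuronal marker lower. These 4 lists had adjusted p-values of 0.543, 0.293, 0.698 and 0.976 with limma's cameraPR. For the histone, epithelial and neuronal lists of the knockdown comparison the direction of the test was opposite to that of the list median, and for the NRF2 list the mean and the median differed in sign.

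**Figure D2:**
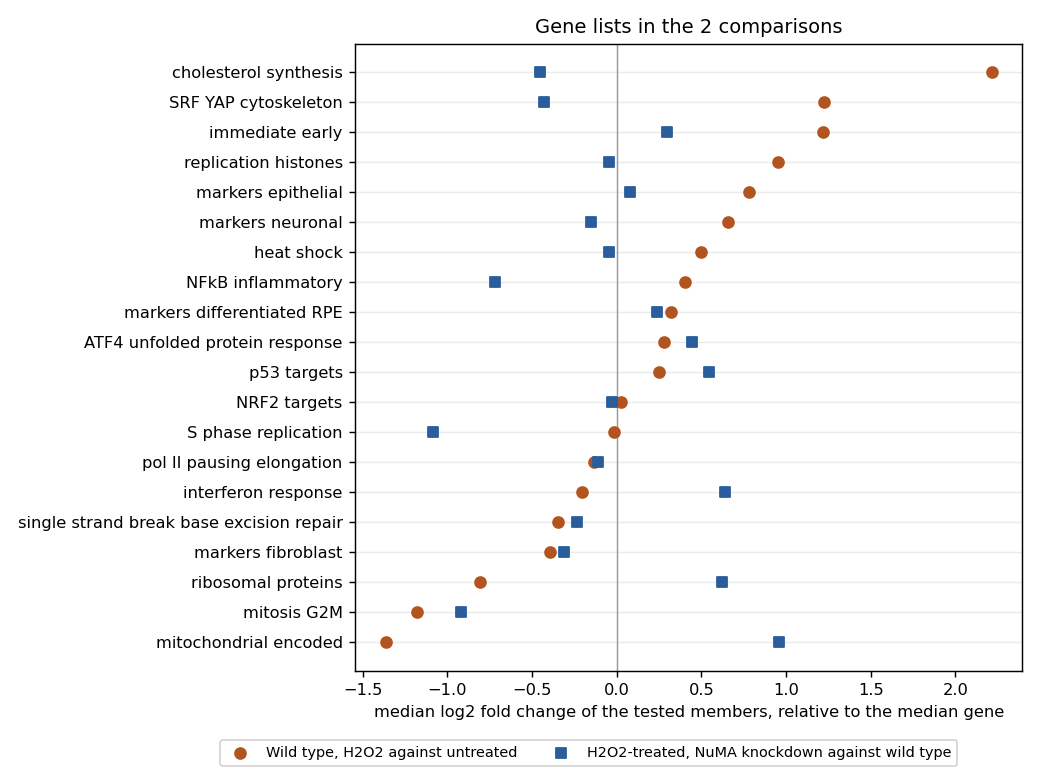
Median log2 fold change, relative to the median gene, of the tested members of each of 20 gene lists in both comparisons (circles, H2O2 against untreated in wild type; squares, knockdown against wild type after H2O2). Cholesterol synthesis genes stand at 2.22 after H2O2 and at -0.45 in the knockdown, ribosomal protein genes at -0.81 and 0.62.

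The comparisons were then set beside each other, gene list by gene list, beside the numbers expected if the calls of a list's members were independent between comparisons. Of the 20 tested cholesterol synthesis genes, 15 rose after H2O2 and fell in the knockdown (13.5 expected), and so did 10 of the 20 SRF and YAP targets (11.1 expected). Of 74 ribosomal protein genes 27, and of 13 mitochondrially encoded mRNAs 11, fell after H2O2 and rose in the knockdown (25.2 and 9.31 expected). Among 26 genes of mitosis 14 fell in both comparisons (15.2 expected). Of 34 immediate early genes, 10 rose in both and 6 rose after H2O2 and fell in the knockdown (10.7 and 6.88 expected). These numbers lay near those expected. In the cholesterol, SRF and YAP, mitochondrial and mitosis lists most members were called in each comparison, which nearly fixes the overlap. Their numbers therefore cannot show whether the comparisons are linked gene by gene within a list. The ribosomal and immediate early numbers gave no sign of such a link. In 100 simulations of unchanged groups against the shared libraries 0 members of any list were called in both comparisons. Where no gene is changed, hardly any passes the adjusted threshold in either comparison, so this result says little. Among changed genes the shared libraries still favour reversals, and part of the reversals may come from them.

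Both comparisons contained the H2O2-treated wild type libraries, with opposite sign, so that their fold changes are negatively related with no effect at all. Over all 17647 genes tested in both, 2404 were higher after H2O2 and lower in the knockdown in the authors' deposited table, against 1435 for independent lists of the same sizes. The other overlaps were 330 higher in both (347 for independent lists), 285 lower then higher (122) and 397 lower in both (504). After centring, 927 genes were higher then lower (458 for independent lists) and 843 lower then higher (458), while 453 were higher in both (491) and 367 lower in both (428). Across these genes, which are not independent replicates, the log2 fold changes had a Pearson r of -0.197, a Spearman rho of -0.200 and a covariance of -0.154. In 100 simulations of unchanged groups against the same libraries the mean r was -0.500 and the mean covariance -0.139 with the spread of the H2O2 comparison (range -0.149 to -0.129) and -0.141 with that of the knockdown comparison. Over 11320 genes with at least 50 mean counts the covariance was -0.0903, against -0.0318 and -0.0187 in the simulations. The shared libraries could not be split, because the tables hold 1 value per group, so part of the excess in the overlaps may come from them.

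**Figure D3:**
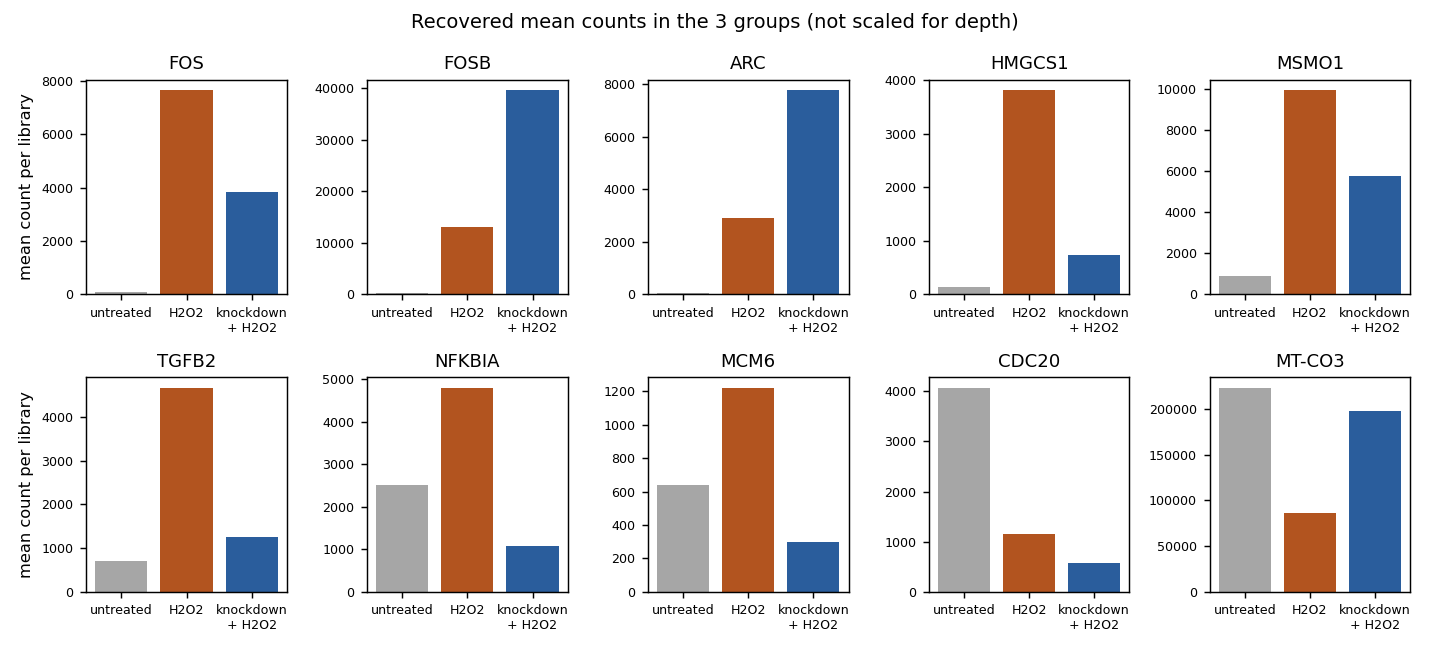
Recovered mean counts per library, not scaled for depth, of 10 genes in untreated wild type (grey), H2O2-treated wild type (brown) and H2O2-treated knockdown cells (blue); no error bars can be drawn because each group has 1 deposited value. HMGCS1 goes from 122.5 to 3820.5 and 738, FOSB from 156.5 to 13025 and 39704.5, and MT-CO3 from 223687.5 to 86694.5 and 198252.5.

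Fold changes were also set against gene span, because a change in elongation could depend on gene length. Elongation itself was not measured. Across 18355 genes, which are not independent replicates, the log2 fold change after H2O2 rose with span (Spearman rho = 0.114). Its median was -0.10 in the shortest of 5 equal groups of genes (median span 1.49 kb) and 0.21 in the longest (median span 142 kb). In the knockdown the relation was the opposite (rho = -0.154 over 18107 genes), with medians of 0.16 in the shortest group and -0.12 in the longest. Over genes with at least 50 mean counts the rho was 0.265 after H2O2 and -0.239 in the knockdown. In the knockdown the fold change also rose with the GC content of the transcripts (rho = 0.268), and longer genes had lower GC content (rho = -0.275). After H2O2 the rho with GC content was 0.0132. Over genes with at least 50 mean counts the rho with GC content was -0.0898 after H2O2 and 0.342 in the knockdown.

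**Figure D4:**
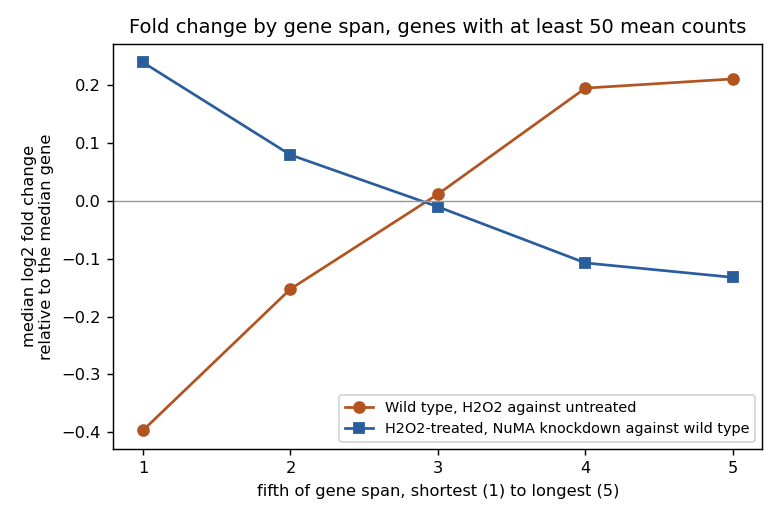
Median log2 fold change, relative to the median gene, in 5 equal groups of genes ordered by genomic span, for genes with at least 50 mean counts (circles, H2O2 against untreated in wild type; squares, knockdown against wild type after H2O2). After H2O2 the medians run from -0.40 in the shortest genes to 0.21 in the longest, and in the knockdown from 0.24 to -0.13.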

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

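The scalings (on the median gene, by total counts and by those of genes with a settled length), the removal of the trends with span and GC content, the ranks and the inter-gene correlation of 0.05 were tests chosen only after the result was seen; the thresholds, the filters on low values and the other measures of gene length were planned. No paired analysis was possible because the tables hold 1 value per group. For the same reason the alternatives with TMM, median-ratio or library-size normalization, DESeq2, limma-voom, all 6 libraries in a single fit, each library left out, other pseudocounts, the shared libraries split, an estimated inter-gene correlation and fry were not run. The spread between libraries is therefore known only through the deposited p-values, and the weight of any single library is unknown.

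The split of the called genes moved most. After H2O2, 4947 genes were higher and 1778 lower in the authors' deposited table, against 3067 and 2921 centred on the median gene, 2963 and 3011 scaled by total counts, 3296 and 2696 scaled by those of genes with a settled length, and 2784 and 904 with a minimum of 2-fold. All 3067 genes higher after centring were among the 4947, and all 1778 lower genes remained lower. In the knockdown, 1244 genes were higher and 5118 lower, against 2829 and 2637 centred, 1800 and 3920 scaled by totals, 1626 and 4234 by those of genes with a settled length, and 180 and 1498 with a minimum of 2-fold. All 1244 higher genes remained higher after centring, and the 2637 lower genes were among the 5118. The scalings shift all fold changes by a constant, which by construction moves calls from one direction to the other. With a threshold of 0.01 there were 3660 higher and 1247 lower genes after H2O2, and 875 and 4071 in the knockdown. Both filters on low values left 4223 and 3586 higher and 1643 and 1361 lower genes after H2O2, and no filter left 4589 and 1596.

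NUMA1 was called lower in the knockdown at a log2 change of -0.75 in the authors' deposited table, at -0.46 centred and at -0.63 scaled by totals. Of 182 values of named genes, 166 kept their direction and side of the threshold after centring, 14 lost and 1 gained a call, and 1 changed direction; by totals these were 168, 13, 1 and 0. The value that changed direction was that of MITF in the knockdown, called in neither test, at -0.18 in the authors' deposited table and 0.11 after centring. Of the 20 lists, 10 were called after H2O2, and between 7 and 12 under the alternatives; in the knockdown 13 were called, and between 11 and 13. The correlation of the fold changes was -0.197, and between -0.214 and -0.182 under the alternatives. The rho with span rose from 0.114 to 0.265 after H2O2 and went from -0.154 to -0.239 in the knockdown over genes with at least 50 mean counts; the cause was not tested. With exonic length in place of span it was 0.0925 and -0.151.

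Low counts limit the smallest genes: the implied standard error had a median of 0.29 over tested genes in the H2O2 comparison against 0.21 over those with more than 500 mean counts.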

Other observations

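The tests of total counts in both comparisons, of GC content in the knockdown, of low counts and of sense-intronic genes were chosen only after the result was seen, and all the classes described here were picked after their values were seen; the tests of mitochondrial share, of GC content after H2O2, of RNA without a poly(A) tail and of genes past gene ends were written before their results. Genes annotated as small nuclear RNA, a class that includes the RNA parts of the splicing machinery, were taken without a filter for spliceosomal genes or pseudogenes. They were higher after H2O2 in 32 of 50 tested cases and lower in 1 in the authors' deposited table, and in 30 and 1 after centring. Their summed mean counts went from 225 in untreated wild type to 3224 in H2O2-treated wild type and 1452 in knockdown libraries. RNU5A-1 went from 45.5 to 602 and 442 mean counts and rose by 3.41 ± 0.27 on the log2 scale after H2O2. RNU4ATAC, of the minor spliceosome, went from 5.5 to 206.5 and 48.5, and RNU4-2 from 1 to 104 and 38. In the knockdown 20 of 49 were lower and 15 after centring. Many of these genes have near-identical copies, so counts of single genes are uncertain.

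The mitochondrial ribosomal RNAs moved apart from the mitochondrially encoded mRNAs after H2O2. MT-RNR1 rose by 2.48 ± 0.20 on the log2 scale, from 9493.5 to 64901.5 mean counts, and MT-RNR2 by 1.11 ± 0.19, while 12 of the 13 mRNAs were lower after centring. In the knockdown they rose by a further 0.80 ± 0.07 and 0.48 ± 0.07. Nuclear copies of mitochondrial sequence leave part of these counts uncertain. No biological explanation was tested.

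Most called genes were higher after H2O2 (73.6%) and lower in the knockdown (80.4%). After H2O2 a difference in total counts left in the fold changes is a candidate explanation. Scaling by the totals gave 49.6% higher, or 55.0% with genes of a settled length only. The log2 ratio of totals, 0.31, lay near the median of 0.29, so this scaling shifts the fold changes much as centring does. The even split is therefore no separate evidence. In the knockdown totals alone do not account for it, since 68.5% were still lower after that scaling (72.3% with genes of a settled length). Mitochondrial transcripts may make up part of the rest but not all of it. The log2 ratio of totals was -0.12 with them and -0.20 without them (-0.18 over genes of a settled length), against a median of -0.29. A general change in the output of newly made RNA stays open in both comparisons, as no spiked-in RNA was analysed here and depth and output cannot be separated.

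Fold changes rose with gene span after H2O2 and fell with it in the knockdown. The H2O2-treated wild type libraries entered both comparisons with opposite sign. A trait of those libraries alone could thus give both relations, and this could not be tested with 1 value per group. GC content does not account for the relation after H2O2, where the partial rho with span given GC content was 0.122, nor do low counts, since the rho was 0.265 over genes with at least 50 mean counts. In the knockdown the partial rho was -0.0865 over all tested genes, between the bounds set for the test, and -0.123 over genes with at least 50 mean counts, so GC content may account for part of that relation but, in the latter genes, not for all of it. More unlabelled mature RNA in the untreated libraries would raise sense-intronic genes after H2O2 against the protein-coding genes whose introns they lie in. Instead 15 of them with at least 50 mean counts lay below their host genes, by a median of -0.86 (12 below and 3 above, sign-flip p of 0.00766). So did those of 37 host genes with a minimum of 20 (median of -0.46) and of 171 with none (median of -0.60). Against all protein-coding genes, the comparison tried first, 21 differed by -0.29 (permutation p of 0.130) and all 229 tested ones by -0.52 (permutation p of 1e-05, the smallest 100000 resamples can give). However, sense-intronic genes are shorter than their hosts, and shorter genes had lower fold changes after H2O2. A value below the host can thus follow from the relation itself, and a sense-intronic gene may also hold mature RNA of its own. The test cannot decide, and this explanation stays open. An effect of H2O2 on elongation stays open as an untested biological explanation.

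More RNA without a poly(A) tail in the H2O2 libraries is a candidate explanation of the rise of small nuclear RNAs. Of 6 listed RNAs of other kinds without a tail, 1 was called higher, RN7SK, which went from 134 to 556 mean counts. The test had been set to count against the explanation at 2 or fewer, but that bound was wrong, because the other 5 had at most 2.5 mean counts and no adjusted p and so could not be called. Other classes taken to be without a tail, looked at after their values were seen, disagreed. Replication-dependent histone genes were higher in 9 of 18 cases after centring, but whether their RNA lacked a tail here was not tested. Of 33 small nucleolar RNA genes 5 were higher and 6 lower, with a median of 0.09, which goes against the explanation. The criterion for the 6 RNAs was revised after their values were seen, and the explanation stays open because 6 small nucleolar RNA genes had at least 50 mean counts (3 higher and 3 lower), most such genes lie in introns of other genes whose reads they may share, and a rise in transcription of the small nuclear RNA genes cannot be told apart from it.

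Transcription past gene ends after H2O2 was tested as a hypothesis on genes with low counts just downstream of expressed genes. Those on the same strand as the upstream gene, 946 genes, had a median of 0.45 on the log2 scale and those on the opposite strand, 304 genes, of 0.51, a difference of -0.0628 with a permutation p of 0.420. The test had been set to count against the hypothesis where the median was not higher. That criterion was revised after the value was seen, because the strand of counting is unknown and without strand both sets would take up such reads alike, so the test could not decide.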
